A study of Homo sapiens with 60 samples.

How the data were processed

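The samples were HepG2 cells treated for 24 h, with total RNA made into directional libraries and sequenced as 100 bp paired-end reads on an MGI instrument, per the labels. The labels state that RNA integrity numbers were above 7 and that some samples with little RNA were left out by the authors. The highest dose was the concentration that inhibited 20% of growth where that lay under 500 µg/mL, otherwise 500 µg/mL, followed by 1/5 and 1/25 of it, per the labels. The sample label gives 0.1% DMSO and the series text 2%, and which of them applied was not settled here. The titles and descriptions of the Coptidis and Zizyphi libraries give different batch letters.

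The deposited values are RSEM expected counts per gene, as the authors supplied them, and were not normalized. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with GRCh38. The annotation release is not given in the sources used here. The table held 60675 Ensembl genes in 267 columns, of which 207 belonged to no sample used here and were not used. Of the values used 8.75% were not whole, and expected counts were rounded to whole numbers before testing. Names came from a gene name table, which matched 56558 IDs, and positions from GENCODE 29 on GRCh38. Of the tested genes 1672 had no symbol. RSEM divides reads that match several genes, so values of pseudogenes, read-through transcripts and close paralogs are uncertain. Library totals of 18015555 to 29549531 counts set the precision of low counts. Every pair of replicates differed by more than sampling noise, so each library was counted once.

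Differences were tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3 after TMM scaling. The 57 libraries of the 22 replicated groups were fitted together, with 1 coefficient per group, so that all groups shared the estimate of the spread (35 residual degrees of freedom, common biological coefficient of variation 6.14%). The filter of edgeR by group kept 16675 genes and left out 44000. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with SE, and levels as TMM-scaled CPM with SD. The SE is an approximation, the absolute log2 fold change divided by the square root of the quasi-likelihood F. Where a group had no counts, the fold was bounded with a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with a 95% counting interval. Gene lists fixed before the data were examined were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over 784 tests (28 lists in 28 comparisons). Within a list, genes were counted at the adjusted p over all genes, and also adjusted over the list alone. The comparison of Citri with Cimicifugae had no list test. Banhasasim-tang, with 1 library per dose, was described by log2 ratios to the vehicle mean with a prior count of 2, and its list medians by their percentile among 10000 random lists of the same size and matched expression.

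The genes named were chosen by a rule written before the data were examined. For each high dose it took the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in the high-dose or vehicle group, with each high-dose library beyond each vehicle library, the same sign in high against low dose and a gene symbol. It added, from each list that camera called, in order of p until about 30 names were reached, up to 3 called members with the largest change in the list's direction. A panel with CYP1A1, HMOX1, DDIT3, CDKN1A and ALB was read in each extract, and some genes that the rule takes are not reported here. For Banhasasim-tang the rule took the panel and the 5 highest and 5 lowest ratios of the high-dose library to the nearest vehicle library, at a mean of at least 5 CPM and with the same sign at the medium dose. Values of these genes at other doses or in other comparisons follow from the rule's names.

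Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE scaling, no filter (33790 genes), the replicate number as a block, a separate fit of each extract with vehicle, leaving out each library in turn (57 refits), camera with an estimated correlation, list members of at least 1 CPM, genes of at least 10 CPM for the similarity between extracts, and a prior count of 5. Added after seeing the data were a fit without replicate 3 of the Bupleuri low dose, offsets per library from a spline (4 degrees of freedom) on GC content and transcript length, which 99.3% of tested genes had, and the Banhasasim-tang medium dose in place of the low dose. Replicate numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their group means, where only Bupleuri high against low (0.116 to 0.284) and Citri against Cimicifugae (0.123 to 0.412) had each of 3 pairs above 0.1. The tests were tested on simulated data drawn from the means and library sizes of these samples over 16264 genes. In simulated Citri high dose against vehicle, edgeR recovered 69.5% of 95 genes changed 1.5-fold and 78% of 100 genes changed 2-fold with 5 unchanged genes called, and in simulated Zizyphi high dose against vehicle 70.5% and 78% with 6. A simulated GC trend in Citri low dose against vehicle gave 442 false calls over 16265 genes without offsets and 0 with them. The calling of vehicle comparisons shares 3 vehicle libraries, and correlations of such comparisons are given beside values simulated for unchanged groups.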

Results

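RNA was sequenced from HepG2 cells, an established human liver cancer line that keeps many hepatocyte functions, after 24 h with an ethanol extract of a medicinal plant material or formula, or with the DMSO vehicle. The 60 libraries form 25 groups. They comprise 3 vehicle libraries and 3 doses of each of 8 extracts. Coptidis Rhizoma (280, 56 and 11.2 µg/mL) and Zizyphi Fructus (500, 100 and 20 µg/mL) had 2 libraries per dose. Citri Unshius Pericarpium, Cimicifugae Rhizoma and Aconiti Lateralis Radix Preparata (each 500, 100 and 20 µg/mL) had 3 per dose, as did Bupleuri Radix (280, 56 and 11.2 µg/mL). The formula Yijung-tang (500, 100 and 20 µg/mL) had 2 per dose, and the formula Banhasasim-tang, at the same doses, had 1. By the labels' dose rule, 280 µg/mL of Coptidis and Bupleuri was the concentration that inhibited 20% of growth. The other extracts were given the upper limit of 500 µg/mL. Library totals ran from 18015555 to 29549531 counts. Each extract was compared with vehicle at each dose, and its highest with its lowest dose. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The vehicle libraries carry a set name of their own in the titles, so set and treatment cannot be told apart in comparisons with vehicle, while the high and low doses of an extract share a set. Counts of called genes are followed by the value without replicate 3 of the Bupleuri low dose, a library that stood apart from its group in its dependence on gene length and whose removal was chosen after seeing the data. Where no other value is given, the calls made for gene lists with a preset correlation held with an estimated correlation. Intervals and floors below cover counting error only.

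**Figure D1:**
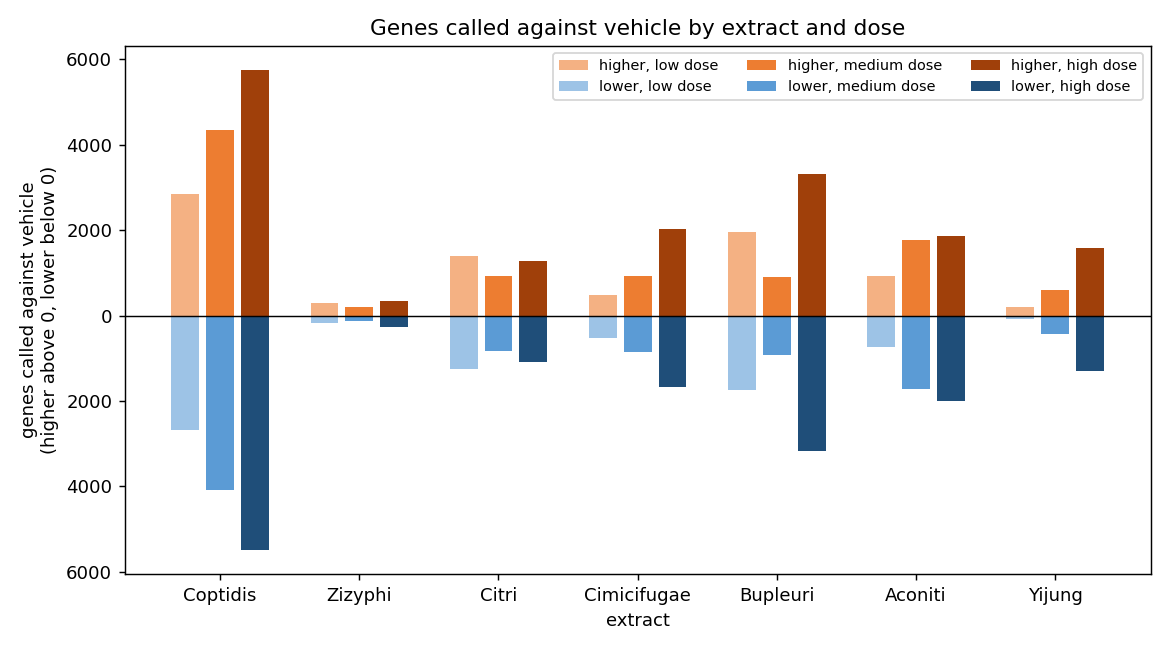
Number of genes called against vehicle at an adjusted p under 0.05 (edgeR's quasi-likelihood test), by extract and dose, with bars above 0 for higher and below 0 for lower genes. The Coptidis high dose has 5755 higher and 5500 lower genes, and the Zizyphi high dose 345 and 261.

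Coptidis Rhizoma, whose main alkaloid is berberine, gave the largest number of called genes. At 280 µg/mL, CYP1A1, a xenobiotic-metabolising enzyme induced through the aryl hydrocarbon receptor (AhR), rose from 12.9 ± 0.704 CPM (counts scaled to a library of 1e+06 counts; SD, n = 3) in vehicle to 4727 ± 57.4 CPM (SD, n = 2), a 367-fold increase. All 8 AhR targets rose (median log2 fold change 6.93), among them CYP1B1 with a log2 fold change of 7.46 ± 0.45 (SE). SLC7A11, the cystine importer, rose 19.0-fold and TXNRD1, a thioredoxin reductase, 7.06-fold, within a list of targets of the oxidative stress regulator NRF2 of which 13 of 14 rose and 1 fell. CDKN1A, the cell cycle inhibitor p21, rose from 95.2 ± 1.92 to 762 ± 2.13 CPM. Of 20 cholesterol synthesis genes and regulators 19 fell and 1 rose, with IDI1, an isoprenoid isomerase, 6.92-fold lower. Both the mitosis list (18 of 18) and the DNA replication list (16 of 16) fell, with the kinesin KIF20A 11.1-fold lower.

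These comparisons used edgeR's quasi-likelihood test, in which the adjusted p was 4.3e-36 for CYP1A1 (chromosome 15, 74719542 to 74725610), 5.2e-35 for SLC7A11 (chromosome 4, 138164097 to 138242349), 5.8e-35 for IDI1 (chromosome 10, 1039152 to 1049170) and 3.6e-31 for KIF20A (chromosome 5, 138178719 to 138187715). Among targets of ATF4, the transcription factor of the integrated stress response, 13 of 15 rose and 1 fell, with ATF3 13.1-fold higher and DDIT3 at a log2 fold change of 1.62 ± 0.11. Of the p53 targets 14 of 16 rose and 2 fell. All 10 fatty acid synthesis genes fell (median −1.21), as did 14 of 16 secreted hepatocyte proteins (median −0.91), with ALB, which encodes albumin, at −0.50 ± 0.05. Of 14 ER chaperones 11 fell and 2 rose. In the cholesterol list INSIG1 had 0 counts against 13 in vehicle, at least 2.46-fold lower. The list median was −2.21, or −2.15 with INSIG1 at its bound. The log2 fold change of CCNA2, a cyclin, was −3.01, that of AURKB, a mitotic kinase, −3.48, and that of the replication factors CDC6 and GINS2 −2.71 and −2.97. Camera gave adjusted p of 9.0e-19 for AhR targets, 2.6e-21 for NRF2 targets, 1.1e-33 for cholesterol synthesis, 2.0e-34 for mitosis and 5.8e-31 for DNA replication. The lists of PXR and CAR targets (6 of 8 higher, 1 lower) and of lysosome genes (11 of 15 higher, 3 lower) had adjusted p of 0.0253 and 3.5e-04, and adjusted p = 0.134 and 0.108 with an estimated correlation. PXR and CAR targets also lost the call among members above 1 CPM, at an adjusted p of 0.0632.

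The largest rises with Coptidis were in genes almost silent in vehicle. MUC5AC, a mucin, was at 96.9 ± 9.06 CPM against 0.0904 ± 0.0506. With 0 counts in vehicle, the complement receptor C5AR2 was at least 1.73e+03-fold higher and MLPH at least 225-fold. TMEM156, at 2 counts in vehicle, had a ratio of 1.57e+03 with a 95% counting interval from 434 to 1.3e+04, and CYP1A2 a ratio of 889 (159 to 3.52e+04). For CHAC1, an ATF4 target, the ratio was 22.9 (5.74 to 199). The largest falls were in ACSM2A, FAM111B, the pseudogene ACSL3P1 and LGALS2, with log2 fold changes of −5.27, −4.76, −4.54 and −4.41. Reads of ACSM2A and ACSL3P1 may be divided with near-identical copies, so their values are uncertain. The dose series ran from a CYP1A1 log2 fold change of 3.05 at 11.2 µg/mL to 6.56 at 56 and 8.52 at 280 µg/mL. HMOX1, haem oxygenase, was −0.50 at the medium and 0.92 ± 0.06 at the high dose. In total 11255 of 16675 tested genes were called at the high dose (5755 higher, 5500 lower), of which 4422 by at least 2-fold, and 11774 in the reduced set of libraries. The medium dose had 8446 (9349 in the reduced set), the low dose 5541 (6720) and high against low 10042 (10679). Without replicate 3 of the low dose, the low-dose count was 3430. Mitochondrial rRNA took 5.54 ± 0.187, 10.9 ± 0.88 and 11.7 ± 0.16% of counts at the high, medium and low dose (SD, n = 2), against 2.52 ± 0.0761% in vehicle (n = 3).

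**Figure D2:**
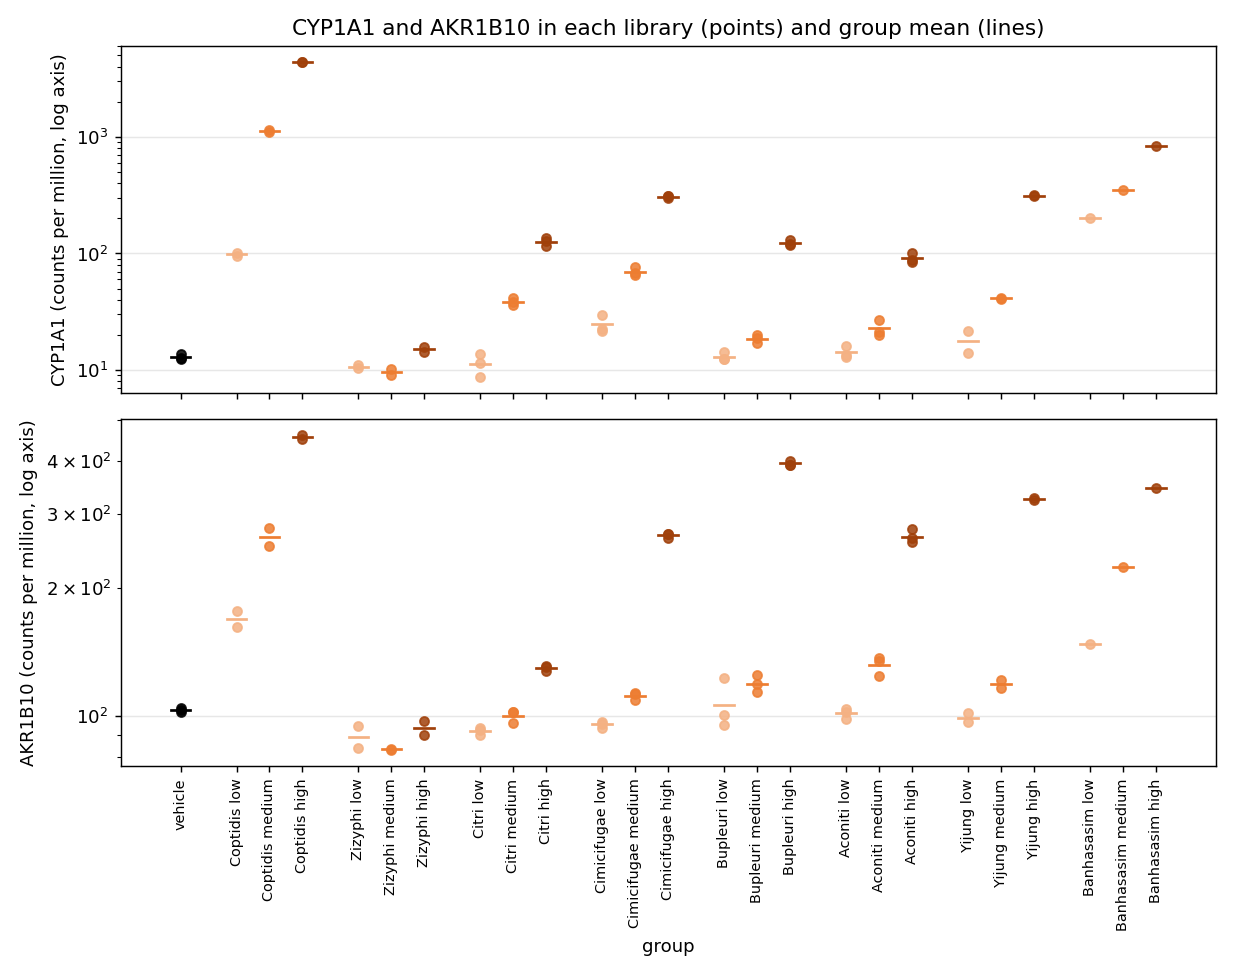
CYP1A1 and AKR1B10 in each library, in CPM of the unscaled library total on a log axis, by extract and dose. Points are libraries and lines group means, and the Coptidis high dose has the highest CYP1A1 mean (4727 CPM after TMM scaling).

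Zizyphi Fructus, the jujube fruit, gave few and small differences. At 500 µg/mL, ASNS, asparagine synthetase and an ATF4 target, was 1.51-fold lower than in vehicle, at 28.9 ± 1.46 CPM (SD, n = 2) against 43.6 ± 0.657 (n = 3). MARK2, a microtubule affinity-regulating kinase, was 1.65-fold higher, at 56.3 ± 1.32 against 34.1 ± 3.55 CPM. The ATF4 target list was lower (median −0.20) with 3 of 15 members lower over all genes and 4 when adjusted over the list alone, including PSAT1 (−0.20 ± 0.04) and STC2 (−0.28 ± 0.07). For ASNS (chromosome 7, 97852118 to 97872542) and MARK2 (chromosome 11, 63838928 to 63911019) the edgeR adjusted p was 1.9e-06 and 9.5e-09, and both calls held whichever library was left out. Camera gave an adjusted p of 3.1e-04 for the ATF4 targets. CYP1A1 (0.21 ± 0.16, edgeR adjusted p 0.527), ALB (0.08 ± 0.05, 0.379) and DDIT3 (−0.17 ± 0.13, 0.513) did not pass. HMOX1 had a log2 fold change of 0.20 ± 0.06 and an edgeR adjusted p of 0.0525, and passed with DESeq2 (0.0244), with RLE scaling (0.0467), with the replicate block (0.041), in a separate fit of this extract and vehicle (0.0131) and in the reduced set (0.0136). ALB passed with GC and length offsets (0.00195).

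SREBF1, the regulator of fatty acid synthesis, rose by 0.44 ± 0.08 and its target FASN by 0.41 ± 0.12 on the log2 scale (edgeR adjusted p 0.00172 and 0.0431), and 2 of 10 members of the fatty acid synthesis list rose. That list had a camera adjusted p of 9.9e-04, and an adjusted p = 0.326 with an estimated correlation. The mitochondrial mRNAs (median −0.17) and nuclear complex I genes (−0.11) had adjusted p of 0.0134 and 0.0263, and adjusted p = 0.495 and 0.63 with an estimated correlation. Unlike ASNS, MARK2, SREBF1 and FASN did not pass between high and low dose (edgeR adjusted p 1 for each). From high to low dose MARK2 stood at 0.72, 0.64 and 0.55, SREBF1 at 0.44, 0.44 and 0.45 and FASN at 0.41, 0.41 and 0.38, the last without a call at the medium (0.0615) and low dose (0.075). CDKN1A stood at −0.26, −0.24 and −0.23 in the same order, and did not pass between high and low dose either (−0.03 ± 0.06). CDKN1A fell by 0.26 on the log2 scale (edgeR adjusted p 0.00482), a call lost without high-dose replicate 2 (0.113) or 3 (0.0699). The SREBF1 call was lost without high-dose replicate 2 (adjusted p 0.11), and that of PSAT1 without replicate 2 (0.128) or 3 (0.0835), without a filter (0.0946) and with GC and length offsets (0.0634). STC2 lost its call without vehicle replicate 1 (0.0669) or high-dose replicate 2 (0.208) or 3 (0.117), and FASN without any single library of either group (0.0698 to 0.305) and with offsets (0.417). At the high dose 606 genes were called (345 higher, 261 lower), 25 of them by at least 2-fold, and 1724 in the reduced set. The medium dose had 321 (1110 in the reduced set) and the low dose 466 (1288). In a separate fit of this extract and vehicle the counts were 1863, 1189 and 1418 from high to low dose, and with GC and length offsets, chosen after seeing the data, 239 and 238 at the high and low dose. The medium dose gave 588 without a filter. Leaving out 1 library changed the high-dose count to 102 without vehicle replicate 1, 216 without vehicle replicate 2, 22 without high-dose replicate 2 and 75 without high-dose replicate 3. The medium-dose count became 42, 171 and 195 without vehicle replicates 1, 2 and 3, and 84 and 15 without medium-dose replicates 2 and 3. The low-dose count became 89, 174 and 253 without those vehicle replicates, and 23 and 142 without low-dose replicates 2 and 3. Between high and low dose edgeR called 1 gene, ASNS (−0.51 ± 0.08, adjusted p 0.00116), with 461 genes at an unadjusted p under 0.05. DESeq2 also called 1, with 306 at an unadjusted p under 0.05, and edgeR called 3 in the reduced set, 2 in the separate fit, 3 with offsets, 56 without a filter, and 0 without high-dose replicate 3 or low-dose replicate 3 (463 and 424 at an unadjusted p under 0.05).

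Citri Unshius Pericarpium, mandarin peel, raised CYP1A1 9.74-fold at 500 µg/mL, to 126 ± 10.4 CPM (SD, n = 3), with 4 of 8 AhR targets higher (median 0.31). AKR1B10, an aldo-keto reductase among the NRF2 targets, rose 1.26-fold, and 7 of 14 NRF2 targets rose (9 when adjusted over the list alone, with 1 lower). UBD, a ubiquitin-like modifier induced by cytokines, was 1.97-fold lower, at 11.0 ± 0.219 against 21.7 ± 1.19 CPM, and ANKRD1, a target of the YAP coactivator, 1.56-fold lower. FGB, the fibrinogen beta chain, fell from 282 ± 5.57 to 202 ± 4.64 CPM, and 6 of 16 secreted hepatocyte proteins fell (7 when adjusted over the list alone). The edgeR adjusted p was 1.4e-21 for CYP1A1, 7.1e-05 for AKR1B10, 6.5e-10 for UBD (chromosome 6, 29555515 to 29559925), 5.7e-10 for ANKRD1 and 3.4e-10 for FGB. By camera the adjusted p was 6.5e-10 for AhR targets and 7.7e-06 for NRF2 targets. The secreted hepatocyte list (median −0.06) had 1.1e-05, and adjusted p = 0.198 with an estimated correlation. In that list APOH and TTR, both secreted carriers, had log2 fold changes of −0.34 ± 0.06 and −0.39 ± 0.09. OSGIN1 (0.44 ± 0.08) and the ferritin chain FTH1 (0.32 ± 0.07) were among the NRF2 targets that rose. CDKN1A fell by 0.27 on the log2 scale (edgeR adjusted p 8.9e-05). HMOX1 (0.15 ± 0.05, 0.0564), DDIT3 (−0.05, 0.845) and ALB (−0.06, 0.423) did not pass, and HMOX1 passed with DESeq2 (0.0428), in a separate fit (0.0074) and in the reduced set (0.0219).

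The dose series with Citri differed between genes. CYP1A1 stood at −0.20 at 20, 1.56 at 100 and 3.28 ± 0.13 at 500 µg/mL. KISS1R (1.05 ± 0.17), NEURL2 (0.82 ± 0.13), PRR7 (0.90 ± 0.15) and TPGS1 (0.91 ± 0.14), among the largest rises at the high dose, had high-against-low log2 fold changes of at most 0.11. CDKN1A (−0.09 ± 0.05), FTH1 (0.09 ± 0.07), APOH (−0.11 ± 0.06) and TTR (−0.24 ± 0.09) did not pass between high and low dose either (edgeR adjusted p 0.577, 0.795, 0.552 and 0.294). CYP1A2 had a ratio to vehicle of 22.4 with a counting interval from 3.64 to 919. Genes called numbered 2375 at the high dose (1289 higher, 1086 lower, 93 by at least 2-fold) and 3694 in the reduced set, 1753 (3098) at the medium, 2657 (4027) at the low dose, and 130 (357) for high against low. With GC and length offsets the medium- and low-dose counts were 1086 and 906 and high against low gave 293, and a separate fit gave 4028, 3517, 4432 and 428 in the order high, medium, low and high against low. The high-dose count was 1387 and 1569 without vehicle replicates 1 and 2, and 1295 without high-dose replicate 1. At the medium dose it was 847 and 1091 without those vehicle replicates, and 649 without medium-dose replicate 1. At the low dose it was 1431 and 1618 without the same vehicle replicates, and 1227 and 1676 without low-dose replicates 1 and 3. High against low gave 64, 68 and 83 without high-dose replicates 1, 2 and 3, and 68 and 73 without low-dose replicates 1 and 3.

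With Cimicifugae Rhizoma at 500 µg/mL, CYP1A1 was 23.6-fold above vehicle, at 305 ± 6.56 CPM (SD, n = 3). HMOX1 rose 2.83-fold, from 56.2 ± 0.562 to 159 ± 5.34 CPM, AKR1B10 2.58-fold, to 265 ± 2.84 CPM, and GCLM, a subunit of the enzyme that makes the glutathione precursor, 2.38-fold. NRF2 targets rose in 13 of 14 cases (median 0.72) and AhR targets in 6 of 8 (median 1.18). All 7 members of the metallothionein list, which includes the zinc exporter SLC30A1, fell (median −1.19), with MT1F, a metal-binding metallothionein, 2.83-fold lower at 19.9 ± 1.12 against 56.3 ± 3.04 CPM. Of 7 members of the gluconeogenesis list, which includes the binding protein gene IGFBP1 described below, 6 rose. Among them was PCK1, phosphoenolpyruvate carboxykinase, at 0.79 ± 0.13. The edgeR adjusted p was 1.5e-26 for CYP1A1, 2.2e-25 for HMOX1 (chromosome 22, 35380361 to 35394214), 6.0e-23 for AKR1B10 (chromosome 7, 134527592 to 134541408) and 2.8e-15 for MT1F (chromosome 16, 56657694 to 56660698). Camera gave adjusted p of 4.2e-70 for NRF2 targets, 3.9e-20 for AhR targets, 6.3e-28 for metallothioneins and 8.1e-07 for gluconeogenesis. Reads of metallothionein genes may be divided between close paralogs, so single members are uncertain. ER chaperones fell in 9 of 14 cases and rose in 1 (10 and 2 when adjusted over the list alone; camera adjusted p 6.6e-05), with HSPA5, the main ER chaperone, at −0.36 ± 0.03. Mitosis genes fell in 8 of 18 cases (9 when adjusted over the list alone; 8.5e-05).

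IGFBP1, a hepatic binding protein of insulin-like growth factors, rose 3.22-fold with Cimicifugae, to 132 ± 19.6 CPM, and SLC5A11, a sodium-coupled sugar transporter, 3.11-fold. SLC6A14, an amino acid transporter, was 2.01-fold lower (edgeR adjusted p 3.5e-12). TMEM160 stood at log2 fold changes of 2.12, 2.00 and 2.01 at the high, medium and low dose. HMOX1 stood at 0.25 and 0.08 at the medium and low dose, and CYP1A1 at 4.56, 2.42 and 0.91 from high to low dose. CDKN1A (−0.04, edgeR adjusted p 0.568), DDIT3 (−0.09, 0.617) and ALB (−0.10, 0.101) did not pass. CDKN1A passed with GC and length offsets (4.5e-04), and ALB in a separate fit (0.00269) and the reduced set (0.0215). Genes called numbered 3694 at the high dose (2025 higher, 1669 lower, 190 by at least 2-fold) and 5034 in the reduced set, 1782 (3150) at the medium, 1018 (2186) at the low dose, and 1191 (2113) for high against low. A separate fit gave 3786 at the medium dose, 2914 at the low dose and 2683 for high against low, for which offsets gave 1824. The medium-dose count was 1000 and 1128 without vehicle replicates 1 and 2, and 936 without medium-dose replicate 3. The low-dose count was 409 and 498 without those vehicle replicates, and 434 and 397 without low-dose replicates 2 and 3. High against low gave 787 without high-dose replicate 1.

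Citri and Cimicifugae carry the same set name in the titles, so their high doses, both 500 µg/mL, were compared directly. HMOX1 was lower with Citri by a log2 difference (Citri minus Cimicifugae) of −1.35 ± 0.05, GCLM by −1.06 ± 0.05, AKR1B10 by −1.04 ± 0.06 and CYP1A1 by −1.28 ± 0.11. Of the 14 NRF2 targets 13 were lower with Citri, and all 7 metallothionein list members were higher, MT1F by 1.23 ± 0.10. PCK1 differed by −0.54 and IGFBP1 by −0.93 ± 0.13. By edgeR's quasi-likelihood test 679 genes differed (198 higher and 481 lower with Citri, 29 by at least 2-fold), 1256 in the reduced set, 1279 with GC and length offsets, and 444 and 438 without Citri high-dose replicates 1 and 3.

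**Figure D3:**
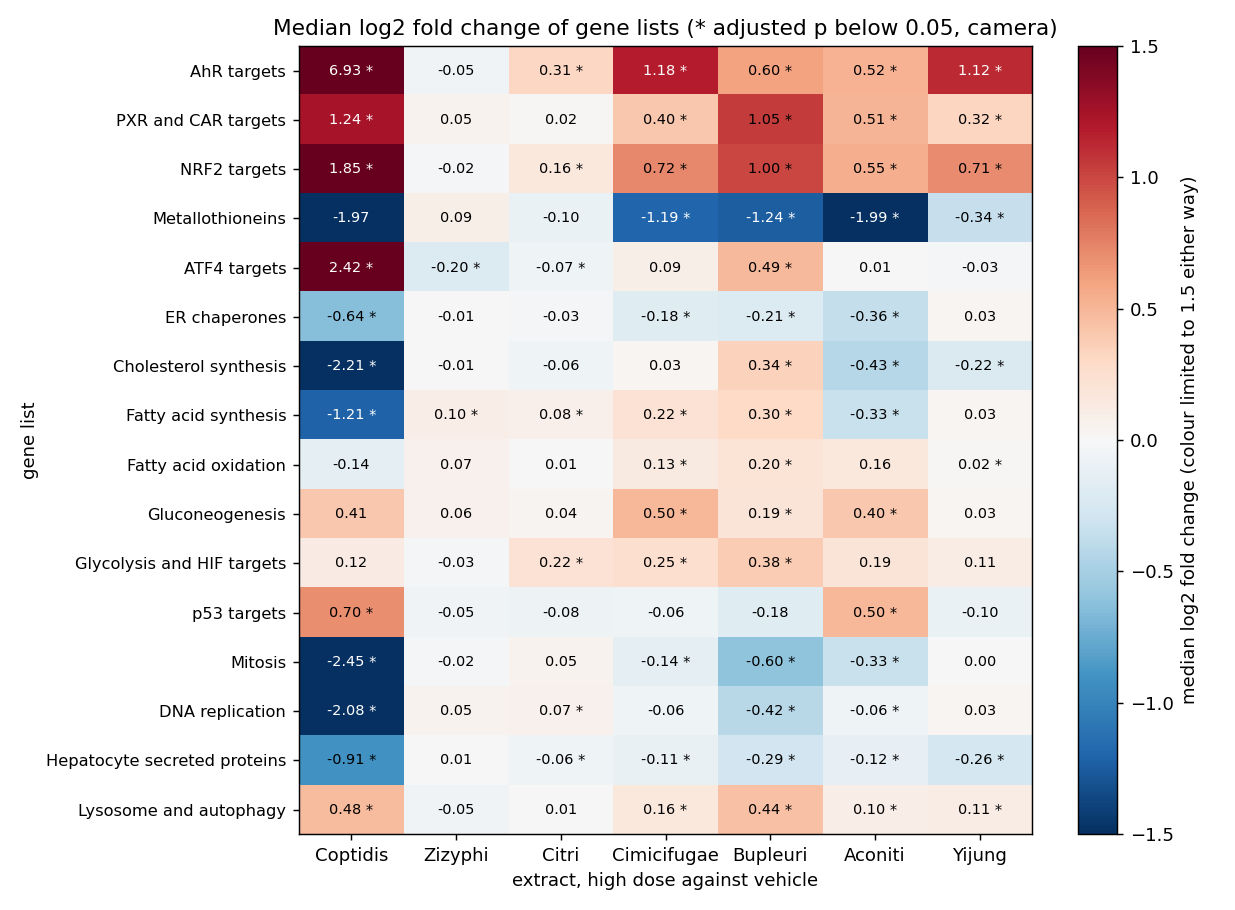
Median log2 fold change against vehicle of 16 gene lists (vertical axis) at the high dose of each tested extract (horizontal axis), with colour limited to 1.5 either side of 0 and an asterisk for a camera adjusted p under 0.05. NRF2 targets are higher with 6 of the 7 tested extracts.

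Bupleuri Radix at 280 µg/mL raised SQSTM1, the autophagy receptor p62, 4.03-fold, from 233 ± 5.10 to 937 ± 13.7 CPM (SD, n = 3), and AKR1B10 3.87-fold, to 397 ± 6.67 CPM. All 14 NRF2 targets rose (median 1.00), and 14 of 15 lysosome and autophagy genes rose (with 1 lower when adjusted over the list alone), among them GABARAPL1, an autophagosome protein, by 1.24 ± 0.09 and MCOLN1, a lysosomal channel, by 0.70 ± 0.09. Of 20 cholesterol synthesis genes and regulators 16 rose with 1 lower (17 and 1 when adjusted over the list alone; median 0.34). Mitosis genes fell in 17 of 18 cases (median −0.60), with KIF20A 1.93-fold lower, DNA replication genes in 15 of 16 (median −0.42), and all 7 metallothionein list members fell (median −1.24). The edgeR adjusted p was 2.9e-31 for SQSTM1 (chromosome 5, 179806398 to 179838078), 4.7e-29 for AKR1B10 and 9.5e-16 for KIF20A. Camera gave adjusted p of 1.4e-45 for NRF2 targets, 1.5e-16 for lysosome and autophagy genes, 6.7e-08 for cholesterol synthesis, 2.3e-25 for mitosis, 3.2e-13 for DNA replication and 1.0e-09 for metallothioneins. Of 15 ATF4 targets 12 rose and 2 fell (3.1e-08), and 6 of 8 PXR and CAR targets rose (1.4e-06). The secreted hepatocyte list (12 of 16 lower and 2 higher, 13 and 2 when adjusted over the list alone; ALB −0.26 ± 0.04) had 5.2e-09, and adjusted p = 0.0688 with an estimated correlation. The gluconeogenesis list, with IGFBP1 among its members, had a camera adjusted p of 0.0443, and adjusted p = 0.15 with an estimated correlation.

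IGFBP1 rose 8.80-fold with Bupleuri, to 361 ± 45.9 CPM from 41.1 ± 2.91, AQP3, a water and glycerol channel, 6.55-fold, CAPN3, a calpain protease, 5.70-fold and RASD1, a small GTPase, 5.56-fold. DKK1, a secreted inhibitor of WNT signalling, was 3.78-fold lower, at 28.9 ± 1.32 against 110 ± 0.998 CPM (edgeR adjusted p 1.5e-25), and SCN1A, a sodium channel subunit, 5.33-fold lower. CYP1A1 rose 9.67-fold at the high dose and stood at log2 fold changes of 0.52 at the medium and 0.00 at the low dose. SQSTM1 stood at 2.01, 0.43 and 0.18 from high to low dose. DDIT3 was at 0.41 ± 0.11 (edgeR adjusted p 0.00194) and lost its call in a separate fit of this extract and vehicle (0.0813). Genes called numbered 6491 at the high dose (3314 higher, 3177 lower, 734 by at least 2-fold) and 7594 in the reduced set, 1822 (3028) at the medium dose and 6711 (5856) for high against low. The low dose gave 3716, and 2051 without its replicate 3. A separate fit of Bupleuri and vehicle gave 4289, 197 and 387 from high to low dose and 4073 for high against low, and offsets gave 2046 at the low dose. The counts of low-dose replicate 3 depended on transcript length with a slope of −0.298 log2 per SD. A fit of the 6 low-dose and vehicle libraries alone called 0 genes by edgeR, the tool run on them, with 1707 at an unadjusted p under 0.05. The low-dose count was 2259 without vehicle replicate 1 and 5697 without low-dose replicate 1. The medium-dose count was 993 and 1176 without vehicle replicates 1 and 2, and 1112 and 1137 without medium-dose replicates 2 and 3.

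With Aconiti Lateralis Radix Preparata, processed aconite root, at 500 µg/mL, all 7 metallothionein list members fell (median −1.99). MT1F was 6.49-fold lower, at 8.70 ± 0.690 CPM (SD, n = 3), MT1E 4.74-fold and MT1G 3.96-fold. SLC39A10, a zinc importer, rose 2.58-fold, from 14.1 ± 0.574 to 36.2 ± 0.606 CPM. All 16 p53 targets rose (median 0.50), with TP53INP1, a p53-induced nuclear protein, 1.93-fold higher, the BH3-only gene BBC3 1.96-fold higher and CDKN1A at 0.39 ± 0.05. Cholesterol synthesis genes fell in 18 of 20 cases (median −0.43), with SQLE, squalene epoxidase, 1.53-fold lower and HMGCS1, HMG-CoA synthase, at −0.63 ± 0.05. AKR1B10 rose 2.51-fold and HMOX1 2.12-fold, within 12 of 14 NRF2 targets that rose with 1 lower (13 and 1 when adjusted over the list alone). The edgeR adjusted p was 3.9e-22 for MT1F, 1.1e-15 for SLC39A10 (chromosome 2, 195575977 to 195737702), 7.4e-15 for TP53INP1 and 4.8e-17 for SQLE. With camera the adjusted p was 1.0e-65 for metallothioneins, 1.2e-28 for p53 targets, 1.6e-36 for cholesterol synthesis and 7.8e-42 for NRF2 targets. Mitosis genes fell in 17 of 18 cases (1.3e-19) and ER chaperones in 10 of 14 with 1 higher (1.1e-14), HSPA5 by 1.51-fold. DDIT3 (−0.21, edgeR adjusted p 0.188) and ALB (0.11, 0.0662) did not pass. DDIT3 passed in a separate fit (0.0288), in the reduced set (0.0403) and with GC and length offsets (0.0469), and ALB in the same settings (0.0045, 0.0187 and 2.6e-05), with DESeq2 (0.0396) and with the replicate block (0.0355).

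CYP1A1 rose 6.90-fold at the high Aconiti dose and stood at log2 fold changes of 0.82 and 0.12 at the medium and low dose. MT1F stood at −2.70 at the high and 0.17 at the low dose, and MT1G was higher than vehicle at the low dose by 0.67 (edgeR adjusted p 4.4e-05). IGFBP1 was 2.65-fold higher at the high dose (1.41 ± 0.14) and at 1.51 at the medium dose. Genes called numbered 3874 at the high dose (1869 higher, 2005 lower, 295 by at least 2-fold) and 5229 in the reduced set, 3487 (4781) at the medium, 1650 (2927) at the low dose, and 2435 (3693) for high against low. A separate fit gave 5302 at the medium dose, 3677 at the low dose and 4133 for high against low. The low-dose count was 833 and 1027 without vehicle replicates 1 and 2, and 890 and 1058 without low-dose replicates 1 and 2. High against low gave 1610 without high-dose replicate 1.

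The formula Yijung-tang, which contains ginseng, ginger, Atractylodes and licorice, raised CYP1A1 24.5-fold at 500 µg/mL, to 316 ± 4.22 CPM (SD, n = 2). AKR1B10 rose from 103 ± 1.76 to 328 ± 3.63 CPM, and all 14 NRF2 targets rose (median 0.71), GCLM by 0.98 ± 0.06 and the steroid reductase AKR1C1 by 0.99 ± 0.07. AhR targets rose in 6 of 8 cases (median 1.12). Secreted hepatocyte proteins fell in 11 of 16 cases (12 when adjusted over the list alone; median −0.26), with FGB at 182 ± 1.21 against 282 ± 5.57 CPM, TTR at −0.64 ± 0.10 and ALB at −0.26 ± 0.05. Cholesterol synthesis genes fell in 12 of 20 cases (median −0.22), with HMGCS1 1.42-fold lower and STARD4, a sterol carrier, at −0.40 ± 0.06. The edgeR adjusted p was 4.1e-26 for CYP1A1, 8.7e-25 for AKR1B10, 5.2e-13 for FGB and 1.3e-09 for HMGCS1. Camera gave adjusted p of 3.3e-66 for NRF2 targets, 3.1e-21 for AhR targets, 2.3e-14 for secreted hepatocyte proteins and 3.3e-08 for cholesterol synthesis. Metallothioneins fell in 5 of 7 cases (median −0.34; MT1F −0.87 ± 0.11), with a camera adjusted p of 1.2e-05 and an adjusted p = 0.0683 with an estimated correlation, and in 7 of 7 between high and low dose (camera adjusted p 2.9e-23). MT1E (−0.47 ± 0.12) lost its call without high-dose replicate 1 (edgeR adjusted p 0.0723).

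Across doses of Yijung-tang, CYP1A1 stood at log2 fold changes of 4.62, 1.67 and 0.47 from high to low. AQP3 rose 2.84-fold at the high dose. SLC6A12, a betaine transporter, was 2.29-fold lower (edgeR adjusted p 1.6e-10), and TMEM160 stood at 2.01 ± 0.24, 2.19 and 1.94 from high to low dose (high against low 0.07, edgeR adjusted p 0.939). CDKN1A (−0.19 ± 0.05, edgeR adjusted p 0.00876) lost its call without a filter (0.109) and without high-dose replicate 1 (0.314), and stood at −0.23 and −0.20 at the medium and low dose. DDIT3 (0.04, 0.879) did not pass. Genes called numbered 2890 at the high dose (1583 higher, 1307 lower, 203 by at least 2-fold) and 4133 in the reduced set, 1042 (2112) at the medium, 281 (811) at the low dose, and 1215 (2023) for high against low. A separate fit gave 5157, 3409, 1898 and 2905 in that order, offsets gave 2019 for high against low, and the low dose gave 538 without a filter. The high-dose count was 1913 and 1396 without its replicates 1 and 2. At the medium dose the count was 555 and 677 without vehicle replicates 1 and 3, and 284 and 309 without its own replicates 1 and 2. At the low dose it was 99 and 152 without vehicle replicates 1 and 2, and 53 and 27 without its own. High against low gave 670 and 644 without high-dose replicates 1 and 2, and 664 and 586 without low-dose replicates 1 and 2.

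Banhasasim-tang, a formula that contains Coptis and jujube, had 1 library per dose, so its differences have no replicate check and no p-value. CYP1A1 was at 881 CPM at 500 µg/mL against 12.6 ± 0.689 CPM in vehicle (SD, n = 3), with log2 ratios of 6.13, 4.84 and 3.97 from high to low dose. IGFBP1 was at 321 CPM against 40.0 ± 2.85, and AQP3 had a log2 ratio of 2.79. SLC6A12 and ACSM2A had log2 ratios of −2.72 and −1.70, and KNG1, which encodes kininogen, was at 1.73 CPM, 4.00-fold below the vehicle mean. BLOC1S5-TXNDC5, a read-through transcript whose reads are uncertain, had 0 counts in the high-dose library and was at least 91.8-fold lower, counting a floor of 3 for that library. All 14 NRF2 targets lay above vehicle (median log2 ratio 0.99) and all 15 ATF4 targets (0.94), medians at the 100th percentile of 10000 random lists of matched expression, where the AhR targets also lay (1.95). All 18 mitosis genes lay below vehicle (median −0.45, percentile 0), and the medians of cholesterol synthesis genes and secreted hepatocyte proteins were −0.34 and −0.44 (percentile 0 each). The random lists drew genes singly from the ratios of the same library, so these percentiles hold no error between libraries. They also take no account of list members varying together. The log2 ratio was 0.39 for HMOX1, 0.50 for CDKN1A, 0.37 for DDIT3 and −0.43 for ALB. Mitochondrial rRNA took 11.8% of counts in the high-dose library (exact binomial 95% interval 11.76 to 11.78%) and 8.01% in the medium-dose library (8.004 to 8.024%), against 2.52 ± 0.0761% in vehicle. In the low-dose library 63.0% of the variance in the gene-wise deviation from the mean of the 57 tested libraries followed GC content and length. Mitochondrial mRNA took 0.585% of its counts (0.581 to 0.588%). The values of the low-dose library, those of CYP1A1 included, are therefore not comparable with the others.

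**Figure D4:**
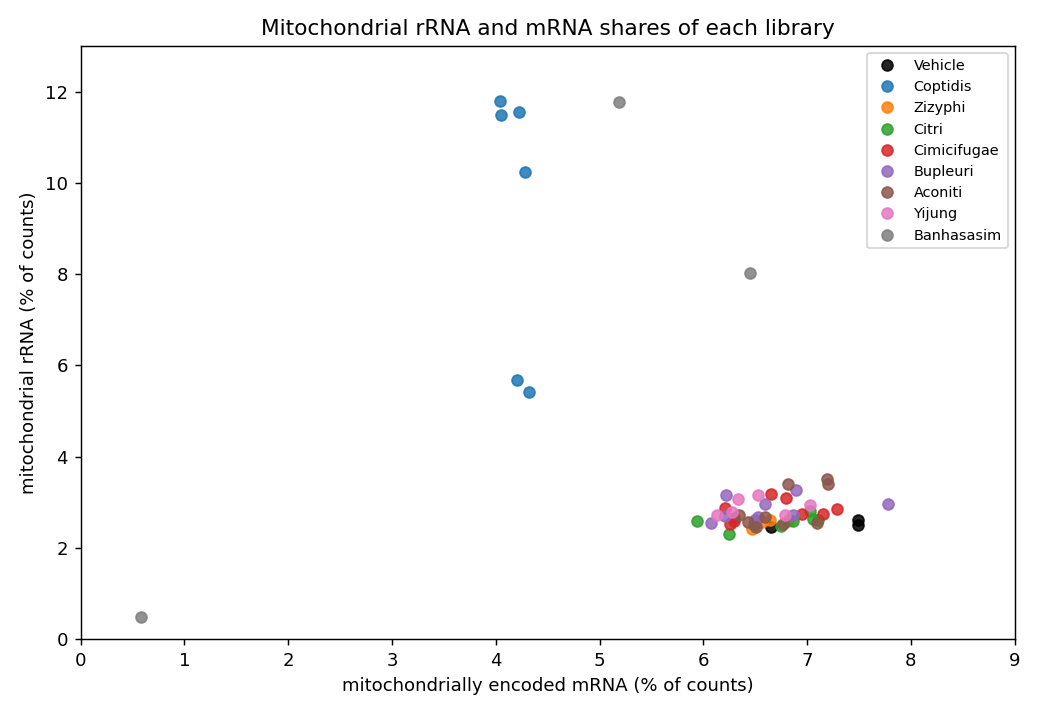
Percent of counts from mitochondrial rRNA (vertical axis) and from mitochondrially encoded mRNA (horizontal axis), with a point per library. Coptidis libraries and the Banhasasim high- and medium-dose libraries lie above all others in rRNA, and the Banhasasim low-dose library lies lowest in both.

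Responses of the extracts were compared through the high-minus-low log2 fold changes over 16675 genes, which share no libraries between extracts. Over all these genes Coptidis and Bupleuri had the highest correlation (r = 0.45 across genes, jackknife SE 0.04), the 1 pair of 21 above 0.3, and r was 0.40 without Coptidis low-dose replicate 3. Only these extracts had a highest dose under 500 µg/mL, which by the labels' rule was set by growth inhibition. A shared degree of growth inhibition therefore cannot be told apart from a likeness of the extracts in this pair. Coptidis and Aconiti had r = 0.18 (0.04), Cimicifugae and Yijung-tang 0.16 (0.06) and Coptidis and Yijung-tang 0.15 (0.05), the last falling to 0.09 without Yijung-tang high-dose replicate 2. The order of the pairs depended on the genes taken. Over 9479 genes with at least 10 CPM these pairs had 0.67, 0.38, 0.67 and 0.27, so that Cimicifugae with Yijung-tang equalled Coptidis with Bupleuri, and other pairs also passed 0.3, among them Citri with Yijung-tang (0.57, from 0.09) and Cimicifugae with Bupleuri (0.52, from 0.13). Genes are not independent replicates, so no p-value is given. Banhasasim-tang had r = 0.15 (SE 0.02) with Coptidis, 0.10 (0.04) with Bupleuri and 0.07 (0.04) with Citri, and at most 0.04 with the other extracts, in a difference that rests on the low-dose library described above. These SEs come from leaving out libraries of the other extract only. They hold no error of the single Banhasasim-tang libraries and are too small for that reason. With the medium dose subtracted instead, chosen after seeing the data, the correlations were 0.31 with Coptidis, 0.27 with Bupleuri and −0.03 with Citri, and the sign with Cimicifugae also reversed, from −0.01 to 0.11. Over genes with at least 10 CPM they were 0.22, 0.14 and 0.25. Without Coptidis low-dose replicate 3 the value with Coptidis was 0.12, and without Citri low-dose replicate 1 that with Citri was 0.03. Against the shared vehicle libraries, Coptidis and Bupleuri had r = 0.56 and a covariance of 0.477, beside 0.45 and 0.0510 in simulated unchanged groups that share controls. Other pairs had a higher r there, up to 0.66 for Cimicifugae with Bupleuri (0.53 simulated), so the pair did not stand out by r. No other pair had as high a covariance. Covariance grows with the size of the fold changes, and these extracts had the most genes called at 2-fold or more at the high dose (4422 and 734). It is therefore no separate sign of likeness. The vehicle group is too small to split, so part of the excess over the simulated values may come from the shared controls.

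Further lists were called at the high dose. AhR targets rose in 5 of 8 cases with Bupleuri (camera adjusted p 2.0e-04) and in 4 of 8 with Aconiti (2.7e-06). PXR and CAR targets rose in 4 of 8 cases with Cimicifugae (6.2e-04) and 5 of 8 with Aconiti (1.0e-04). Members of the gluconeogenesis list, IGFBP1 included, rose in 4 of 7 cases with Aconiti (5 when adjusted over the list alone, camera adjusted p 0.00407). Fatty acid oxidation genes rose in 6 of 10 cases with Cimicifugae (0.00152) and in 5 of 10, with 1 lower, with Bupleuri (2.5e-07). With Yijung-tang 4 of 10 rose (0.00612), where the list's median was 0.02 and its mean 0.00. ER chaperones fell in 9 of 14 cases with Bupleuri, with 1 higher (8.8e-04). Other high-dose calls were lost with an estimated correlation. For Citri these were ATF4 targets (adjusted p = 0.254), fatty acid synthesis (0.522), DNA replication (0.12), glycolysis and HIF targets (0.326) and acute phase genes (0.102). For Cimicifugae they were fatty acid synthesis (0.194), glycolysis (0.177), secreted hepatocyte proteins (0.273), acute phase genes (0.0718) and lysosome genes (0.0737), and for Bupleuri fatty acid synthesis (0.326) and glycolysis (0.194). For Aconiti they were fatty acid synthesis (0.1), DNA replication (0.194), secreted hepatocyte proteins (0.162), acute phase genes (0.113) and lysosome genes (0.241). For Yijung-tang they were PXR and CAR targets (0.121), lysosome genes (0.194) and ribosome biogenesis (0.1).

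Markers of other cell types gave no call in any of 28 comparisons by camera, with a lowest adjusted p of 0.163 for leukocyte, 0.45 for endothelial and 0.0598 for biliary and epithelial markers. The last list was called among members above 1 CPM for high against low with Citri (0.03) and Yijung-tang (0.0487). Only 2 fibroblast markers were measured, too few for a test. LXR targets (lowest adjusted p 0.354), bile acid genes (0.215), interferon response genes (0.251) and nuclear RNAs that mark RNA quality (0.201) were not called. Heat shock proteins were called in Citri high against low (0.021), with an adjusted p = 0.275 with an estimated correlation. Dependence of the counts on GC content differed between libraries. The slopes of the vehicle libraries were −0.113, −0.109 and −0.0877 log2 per SD, and that of the Banhasasim low-dose library was 0.80.

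**Figure D5:**
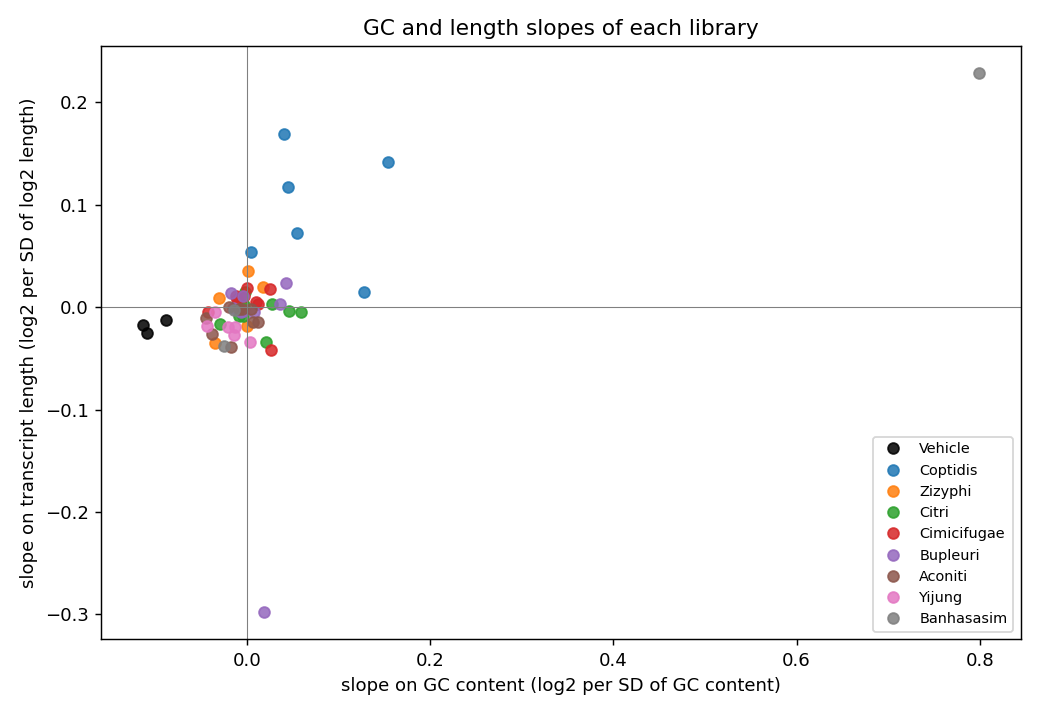
Slope of each library's gene-wise deviation on GC content (horizontal axis) and on transcript length (vertical axis), in log2 units per SD; points are libraries. The Banhasasim low-dose library has the highest GC slope, and replicate 3 of the Bupleuri low dose has a length slope of −0.298.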

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

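The tests of the set of the libraries, of Coptidis Rhizoma in the extract, of distance from the promoter, of the depth of a Bupleuri library, of GC and length offsets and of the fit without that library were chosen only after the results were seen.

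Mitochondrial rRNA took 11.8% of counts in the high-dose and 8.01% in the medium-dose Banhasasim-tang library, which enter no tested comparison, against at most 2.61% in a vehicle library. In Coptidis libraries the ratio of mitochondrial rRNA to mitochondrial mRNA ran from 1.25 to 2.92, against 0.333 to 0.371 in vehicle. A property of the set named in the titles is argued against for Coptidis, because the Zizyphi libraries of the same set reached at most 0.392. Banhasasim-tang carries another set name, shared with Yijung-tang, whose libraries reached at most 0.485. With 1 library per dose, no conclusion on the set is drawn for Banhasasim-tang. A GC or length trend is argued against as the whole cause with Coptidis. At its low dose the rRNA mean minus the median of heavy-strand mRNAs was 3.61 on the log2 scale with offsets and 3.65 without. Coptidis Rhizoma itself, which the formula contains, stays open as an untested explanation: the high- and medium-dose Banhasasim-tang libraries had ratios of 2.27 and 1.24, against at most 0.51 in 51 libraries without Coptidis, but these are the libraries in which the pattern was seen. Loss of heavy-strand RNA with distance from its promoter may also contribute and stays open, as Spearman's rho of log2 fold change and gene start was −0.56 (Pearson's r −0.68, permutation p 0.041, 14 genes, 100000 resamples), but −0.30 (permutation p 0.34) without both rRNAs, which lie next to the promoter and are themselves the pattern. The heavy-strand genes farthest from the promoter, MT-ND5 and MT-CYB, were not called at the Coptidis low dose (−0.10 ± 0.13 and −0.05 ± 0.08). These values go against a steady loss with distance, while rho was −0.94 without both genes. MT-ND6, on the light strand, also fell there (−1.23 ± 0.22).

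Low doses of the extracts called genes against vehicle even where the high and low doses of an extract differed little. A GC or length trend of the vehicle libraries may account for part of this: calls summed over 6 low doses numbered 5553 with offsets and 9788 without, 56.7% as many. The extracts differed in this, with counts of 2657 without and 906 with offsets for Citri, 466 and 238 for Zizyphi, 3716 and 2046 for Bupleuri, 1650 and 1200 for Aconiti, 1018 and 848 for Cimicifugae but 281 and 315 for Yijung-tang, so how much of the pattern the trend accounts for stays open. The covariance of low-dose fold changes between extracts of different sets was at least 2.30 times the simulated covariance in 13 pairs. This was the prediction if the vehicle libraries as a set stood apart from the extract libraries. The simulated libraries had no GC trend, however, so the covariance cannot tell such a set from a GC trend of the vehicle libraries. All 13 pairs also share the same vehicle libraries and are not independent. A shared effect of low doses was not tested and stays open.

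The Bupleuri low dose had 3716 called genes against 1822 at its medium dose. A gene length trend of replicate 3 is a candidate cause of part of this, since the fit without it gave 55.2% as many calls (2051), against 3028 at the medium dose. With offsets the low dose still had more, 2046 against 1662. Low depth of that library is argued against by its total, 22.7 when expressed in units of 1e+06 counts, above 9 other libraries. No biological explanation was tested.

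Each comparison of 3 with 3 libraries has 10 splits of its 6 libraries, too few for a share under 0.05. In fits of the 6 libraries alone, the real split gave 4252, 3691, 4634 and 330 genes for Citri (high, medium and low dose against vehicle and high against low), with at most 0, 1, 1 and 3 in another split. Cimicifugae gave 5092, 4511, 3468 and 2077, with at most 0, 1, 3 and 3. Aconiti gave 5581, 5490, 4161 and 3828, with at most 1, 0, 0 and 1. Citri against Cimicifugae gave 974, with at most 2. Bupleuri gave 7851, 4578 and 1701 for high, medium and high against low, with at most 0 in another split, and 0 at the low dose, where 10 of 10 splits gave as many. In each of the others 1 split, the real one, gave as many. In the 8 comparisons whose other splits each called 0 genes by edgeR, at most 605 genes had an unadjusted p under 0.05 in another split, and the real split of the Bupleuri low dose had 1707. No other tool was run on the splits.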

How the results depend on the processing

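The fits without replicate 3 of the Bupleuri low dose, with offsets for GC content and transcript length, and with the medium in place of the low Banhasasim-tang dose were tests chosen only after the results were seen. Of the 29 counts of called genes, 22 moved by over 1.5 times in separate fits per extract, 19 without the Bupleuri library, 10 with offsets and 3 without a filter. With DESeq2, with RLE scaling and with the replicate block, each of the 29 counts stayed within 1.5 times its value. TMM, RLE and DESeq2 scaling left a median log2 fold change of 0.00, 0.02 and 0.02 at the Coptidis high dose. Their likeness cannot test a shift of most genes in the same direction, so the balance of higher and lower genes rests on the scaling. Of the named values, 201 of 205 kept their side of the threshold with DESeq2 and 4 became called. Of 209, 208 kept it and 1 became called with RLE, 206 and 1 without a filter, with 2 lost, 190 and 4 with offsets, with 15 lost, and 202 and 7 without the Bupleuri library. In separate fits 193 of 207 kept it, 7 became called and 7 were lost. No named gene reversed. Over single left-out libraries 1098 values of named genes kept their side and 71 were lost. Leaving out a library of a group of 2 leaves a lone sample, which is then assumed to vary like the other groups. Depth limits genes near the floor, where folds are bounds or ratios with wide intervals. The alternative for values that are not counts was not run, since the values are counts. The cause of the changes below was not tested.

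In Bupleuri high against low and Citri against Cimicifugae each same-numbered pair correlated above 0.1, and the replicate block gave 6777 and 709 genes. With Bupleuri, high-dose replicate 2 correlated less with its own number (0.116) than with another (0.132), so pairing there is undecided. In the other comparisons the numbers were not taken as pairs, which in those with 2 pairs is undecided: same-numbered libraries correlated at 0.507 for Zizyphi, 0.257 for Coptidis and 0.153 for Yijung-tang between high and low dose, where both pairs of groups of 2 give the same value. With 3 pairs, every library of Cimicifugae high against low correlated best with its own number, a hint from the data and not from the design. The block changed 2 of 393 list results, gluconeogenesis at the Bupleuri high dose (adjusted p 0.093 by camera) and heat shock proteins in Yijung-tang high against low (0.0439), and 4 named genes, of which PEDS1-UBE2V1 with Yijung-tang lost its call (edgeR adjusted p 0.0544). It changed no other call among these list results and named genes, and the counts of other genes called moved by less than 1.5 times.

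In separate fits of each extract with vehicle, the counts for the high, medium and low dose and high against low were 1863, 1189, 1418 and 2 for Zizyphi, 4028, 3517, 4432 and 428 for Citri, 4289, 197, 387 and 4073 for Bupleuri, and 5157, 3409, 1898 and 2905 for Yijung-tang. For Cimicifugae they were 3786, 2914 and 2683, and for Aconiti 5302, 3677 and 4133, from the medium dose on. Without replicate 3 of the Bupleuri low dose they were 1724, 1110, 1288 and 3 for Zizyphi, 3694, 3098, 4027 and 357 for Citri, 4133, 2112, 811 and 2023 for Yijung-tang, 3150, 2186 and 2113 for Cimicifugae from the medium dose on, 3028 and 2051 for the medium and low Bupleuri doses, 2927 and 3693 for the low dose and high against low of Aconiti, and 1256 for Citri against Cimicifugae. Offsets gave 239, 238 and 3 for Zizyphi high, low and high against low, 1086, 906 and 293 for Citri medium, low and high against low, 1824 and 2019 for high against low of Cimicifugae and Yijung-tang, 2046 for Bupleuri low and 1279 for Citri against Cimicifugae. Without a filter Zizyphi gave 588 at the medium dose and 56 for high against low, and Yijung-tang 538 at the low dose.

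Leaving out each library in turn gave ranges of 3430 to 5092 for Coptidis low. For Zizyphi the ranges were 22 to 435, 15 to 195, 23 to 253 and 0 to 1 in the order high, medium, low and high against low, and for Citri 1295 to 1848, 649 to 1660, 1227 to 2519 and 64 to 116. Cimicifugae medium, low and high against low ranged over 936 to 1287, 397 to 796 and 787 to 896, Bupleuri medium and low over 993 to 1346 and 2051 to 5697, and Aconiti low and high against low over 833 to 1178 and 1610 to 2048. Yijung-tang ranged over 1396 to 2401, 284 to 697, 27 to 188 and 586 to 670, and Citri against Cimicifugae over 438 to 493. Of the 784 list tests 245 were called with the preset correlation and 139 with an estimated one, so that 106 lost their call, 48 of them at the high dose or between high and low dose. With members of at least 1 CPM 374 list results kept their side, 3 became called and 2 were lost.

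Over genes of at least 10 CPM the correlation of high-minus-low responses became 0.05 for Coptidis with Citri, 0.32 with Cimicifugae, 0.67 with Bupleuri, 0.38 with Aconiti and 0.27 with Yijung-tang. Zizyphi had 0.12 with Citri, and its signs reversed to 0.16 with Bupleuri and 0.06 with Yijung-tang. Citri had 0.40 with Cimicifugae, 0.16 with Aconiti, 0.57 with Yijung-tang and, reversed, 0.13 with Bupleuri. Cimicifugae had 0.52 with Bupleuri, 0.40 with Aconiti and 0.67 with Yijung-tang. Bupleuri had 0.33 with Aconiti and 0.41 with Yijung-tang, and Aconiti with Yijung-tang reversed to 0.27. Banhasasim-tang had 0.22 with Coptidis, −0.12 with Zizyphi, 0.25 with Citri, −0.05 with Cimicifugae, 0.14 with Bupleuri, 0.16 with Aconiti and 0.10 with Yijung-tang. With its medium dose in place of the GC-dependent low-dose library, it had 0.31 with Coptidis, 0.27 with Bupleuri and 0.10 with Yijung-tang, and the signs with Citri (−0.03) and Cimicifugae (0.11) reversed. With single libraries left out, r ranged over 0.40 to 0.44 for Coptidis with Bupleuri, 0.09 to 0.15 for Coptidis with Yijung-tang, 0.12 to 0.15 for Banhasasim-tang with Coptidis and 0.03 to 0.08 for Banhasasim-tang with Citri. With a prior count of 5 in place of 2, 119 Banhasasim-tang values stayed and 10 moved. The list medians that moved were AhR targets (1.68) and PXR and CAR targets (0.39) at the high dose, and at the low dose AhR targets (0.68), fatty acid oxidation (0.06), endothelial markers (0.86) and biliary markers (0.55).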

Other observations

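The genes and comparisons in this part were chosen after their values were seen, and the tests are those of the report. Between the high and low dose of an extract, which share a set, members of the list of metallothioneins with the zinc exporter SLC30A1 were lower at the high dose in 7 of 7 cases with Aconiti (median log2 fold change −2.47), Bupleuri (−1.75), Cimicifugae (−1.22) and Yijung-tang (−0.84). Camera gave adjusted p of 4.4e-105, 3.8e-17, 1.1e-52 and 2.9e-23, and adjusted p = 6.9e-12, 3.0e-04, 9.3e-09 and 3.1e-05 with an estimated correlation. With Citri 2 of 7 were lower (median −0.23, 5.7e-07; adjusted p = 0.0336 with an estimated correlation). The list was also called as lower with Zizyphi (median −0.26, 1.5e-07; adjusted p = 0.0243 with an estimated correlation), where 0 of 7 members passed by edgeR and the comparison had 461 genes at an unadjusted p under 0.05 (306 by DESeq2), and was not called with Coptidis (0.0757). At the low dose the list was above vehicle with Yijung-tang (median 0.47, 3 of 7 members called and 6 when adjusted over the list alone, with 1 lower; adjusted p 9.9e-11, and 0.00528 with an estimated correlation), and MT1G rose there by 0.91 ± 0.11 (edgeR adjusted p 5.0e-06). It was also called as higher at the low dose of Bupleuri (median 0.51, 6 of 7 higher and 1 lower; 9.5e-05, and adjusted p = 0.115 with an estimated correlation), Aconiti (0.35, 3 higher and 1 lower; 0.00244, and adjusted p = 0.241 with an estimated correlation) and Zizyphi (0.27, 2 higher; 5.5e-06, and adjusted p = 0.0568 with an estimated correlation), and was not called at that of Citri (median 0.26, 0.0663), Cimicifugae (0.03, 0.676) or Coptidis (−0.14, 0.264). The Zizyphi high dose had a median of 0.09 against vehicle (0.433), so its fall between doses starts from a low dose above vehicle. The Bupleuri values for its low dose and for high against low include low-dose replicate 3, whose counts depended on transcript length. The list was not tested without that library. MT1F was at 91.02 CPM of the unscaled total there, against 59.25 and 66.03 in low-dose replicates 1 and 2. It stood at 18.35 to 18.94 in the Bupleuri high-dose libraries and 53.44 to 58.6 in vehicle. With Coptidis the members moved apart: MT2A rose by 2.12 ± 0.11 at the high dose while MT1F stood at −3.28 ± 0.14 and MT1G at −3.17 ± 0.15.

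CPT1A, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, was higher at the high dose with Coptidis (1.44 ± 0.06), Yijung-tang (0.85 ± 0.06), Cimicifugae (0.70 ± 0.06), Aconiti (0.48 ± 0.06) and also Bupleuri, by edgeR's quasi-likelihood test, and stood at 0.09 ± 0.06 with Citri (adjusted p 0.34). PLIN2, a lipid droplet coat protein, rose by 2.71 ± 0.05 with Coptidis and 1.56 ± 0.05 with Bupleuri. IGFBP1, described above for other extracts, had its highest values in the Coptidis high-dose libraries. It was at 5349 and 5952 CPM of the unscaled library total there, against 38.35 to 44.26 in vehicle. GDF15, a stress-induced cytokine, rose by 4.49 ± 0.10 with Coptidis, 2.09 ± 0.09 with Bupleuri, 0.87 ± 0.08 with Aconiti, 0.82 ± 0.08 with Cimicifugae and 0.63 ± 0.09 with Yijung-tang. The fibrinogen chains FGA and FGG stood at −3.81 ± 0.06 and −3.55 ± 0.07 with Coptidis, and at −1.01 ± 0.05 and −0.88 ± 0.06 with Bupleuri. ASNS, lower with Zizyphi, was also lower with Citri (−0.64 ± 0.06, edgeR adjusted p 2.4e-09) and higher with Coptidis (2.72 ± 0.07).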
